A study of Homo sapiens with 6 samples.

How the data were processed

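RNA levels were measured on 6 one-colour Affymetrix arrays of PC-9 cells, a human lung adenocarcinoma line that carries an activating EGFR mutation. Per the labels' protocols, cells were grown in dishes and given medium with 0.5 µM osimertinib, a covalent inhibitor of mutant EGFR, with medium changes along the way, and the cells still alive on day 8 were taken as tolerant. Per the labels' protocols, total RNA was prepared on spin columns and 250 ng per sample was turned into biotin-labelled single-stranded DNA with a whole-transcript labelling kit. Samples were grouped by their titles: 3 arrays of tolerant cells and 3 of naive cells. The source field and the treatment text of all 6 samples speak of 1 week of osimertinib, which goes against the titles, the cell type field and the series design for the 3 naive arrays. The titles, the cell type field and the design text were followed, and when the naive cells were collected is not stated.

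The deposited values are on a log2 scale, 1 value per probe set and array, with 2 decimals. Per the submitters' processing notes the authors used Transcriptome Analysis Console; its version and the normalization and background method are not given in the sources used here. The size of log2 differences and folds depends on that method, so the folds given hold for these values only. The values ran from 2.41 to 17.51. Array medians ran from 7.17 to 7.24 and array 25th percentiles from 4.65 to 4.82, so the deposited log2 values were used without further normalization. No detection p was used here, and no array control probe sets were in the table. A dim probe set can therefore not be told from background, and 4.73, the 25th percentile of the probe set means, serves below only as a mark for low signal. A log2 difference that starts or ends near it can understate the change in RNA, and saturation of the brightest probe sets was not checked. For arrays there is no read depth; the number of arrays limits the precision, and the median SE of a log2 difference was 0.15.

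The table holds 21448 probe sets. GEO's platform annotation gave exactly 1 gene symbol to 17709 of them and several symbols to 0, and 3739 were not listed there and stay unnamed here. All Entrez identifiers were found in NCBI's gene table for GRCh38.p14, and 0 symbols changed. That table was used for names only. No genome build was named for the array values, so no coordinates are given. The named probe sets stand for 17687 genes, of which 20 had more than 1 probe set; the brightest one on average was then used for the gene. ERBB2 was not among the named genes and is not analysed here.

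Tolerant and naive arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) on the log2 values of all 21448 probe sets, with 4 residual and 4.27 prior degrees of freedom. Probe sets with a Benjamini-Hochberg adjusted p under 0.05 were called, and counts at 2-fold or more are given as well. All adjusted p-values for single genes come from this limma test, are two-sided and cover all probe sets. Errors are the SD over 3 arrays per group or the SE of the limma difference. Nothing in the labels says that the arrays of a group came from separate cultures, so p-values measure only the spread among these samples, which may be technical.

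Before the data were examined, 47 gene lists were fixed, covering signalling, cell cycle, metabolism, stress, immune and lineage genes and markers of cells that do not belong in the cultures. A list needed 3 measured members, which left 46. Lists were tested with limma's camera at its preset correlation between genes of 0.01, with adjustment over the 46 lists. Camera was also run with the correlation estimated from the arrays, and fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes, was run as another alternative. With an estimated correlation camera takes its p from the 4 residual degrees of freedom. Its p-values therefore rise even where the estimate is no higher than the preset. Members past the threshold are counted over all probe sets tested and, separately, adjusted over the list alone.

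Genes to be named were also chosen by a rule fixed before the data were examined. They are the 12 largest differences in each direction among called probe sets with 1 symbol whose 2 groups of arrays do not overlap. From each list with a call, the rule takes the 3 largest called members in the list's direction and the largest called member in the other direction. From each list without a call that is described, it takes the 2 largest called members. EGFR, ERBB2, ERBB3, MET, AXL, IGF1R, DUSP6, MKI67, CDKN1A, BCL2L11, NKX2-1, CDH1, VIM, ALDH1A1 and CD274 are named whatever their values. The rule gave 149 genes, 141 of them past the threshold.

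Alternatives were a fit with the replicate number as a block, leaving out each array, leaving out dim probe sets (mean under the 25th percentile or under the median), quantile normalization, centring on 15 reference genes, a trended robust prior, array weights, a threshold of 0.01 and the mean over a gene's probe sets. A fit without 1 array has fewer degrees of freedom, so a call that ends there need not rest on that array. After the data had been seen, each array's 25th percentile as a covariate and a filter on the higher group mean were added. A planned choice between pseudocounts was not run because the values were already logs. The procedure was tested on simulated data with the real arrays' levels and spread. Of planted log2 differences of 1, 32 of 67 were recovered (47.8%), of those of 2, 61 of 66 (92.4%), and of those of 0.5, 0 of 67, with 4 calls among unplanted probe sets out of 21448. Only the planted probe sets differed there, a far smaller share than the 18.2% called in the real data. An adjusted p under 0.05 was therefore harder to reach in the simulation, and these shares do not give the recovery in the real comparison. All 5 of 5 planted list shifts and 0 of 35 other lists were called by camera at both correlations and by fry, on simulated genes that varied independently of each other. Every gene of a planted list was shifted by 0.5 while few other genes differed. These list results do not give the recovery in the real comparison either. Tables were prepared and plots drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.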

Results

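Gene expression was compared between PC-9 cells that had survived 1 week in 0.5 µM osimertinib, here called tolerant, and naive PC-9 cells, with 3 arrays per group. The comparison asks which genes differ in cells that outlive the drug. With only these groups, it cannot tell traits of surviving cells from a direct response to the drug or from time in culture. The source field and treatment text of the 3 naive arrays also mention the drug, so their identity rests on the titles, the cell type field and the design text. Over all 21448 probe sets, arrays of the same group correlated with Pearson's r between 0.994 and 0.996, and arrays of different groups between 0.983 and 0.986. These correlations run across probe sets, which are not independent replicates. The first principal component held 65.5% of the variance and separated the groups, and the second held 14%. No pair of arrays was a copy of another.

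The largest rise in signal was that of VTCN1, which encodes the immune checkpoint ligand B7-H4: its log2 signal was 5.94 ± 0.13 in naive and 12.25 ± 0.19 in tolerant cells (SD, n = 3 each), a 79.3-fold rise (log2 difference 6.31 ± 0.14 SE, adjusted p = 8.3e-07). SLCO2B1, an organic anion transporter, rose 56.6-fold (5.82 ± 0.20 SE), and ABI3BP, an extracellular matrix protein, 41.4-fold (5.37 ± 0.33 SE). The largest fall was that of CEACAM6, a cell adhesion molecule of epithelial tumours, from 12.21 ± 0.17 to 6.77 ± 0.36 (log2 difference −5.44 ± 0.19 SE), followed by CALB1, a calcium-binding protein, at −5.23 ± 0.17 SE. These rises and falls are those of signal and can understate those of RNA, since signal over background was not measured. In all, 2042 probe sets were higher and 1856 lower in tolerant cells, together 18.2% of those tested. The lower count was 1107 without naive array 3 and 1203 without tolerant array 2, and at an adjusted p under 0.01 the counts were 1163 and 772. At 2-fold or more, 757 were higher and 351 lower, of which 57 rises had a naive mean and 30 falls a tolerant mean among the lowest 25% of probe sets. Probe sets without a gene name made up 183 of the higher and 255 of the lower ones. The arrays of the 2 groups did not overlap for 35.6% of all probe sets, against 10% by chance.

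**Figure D1:**
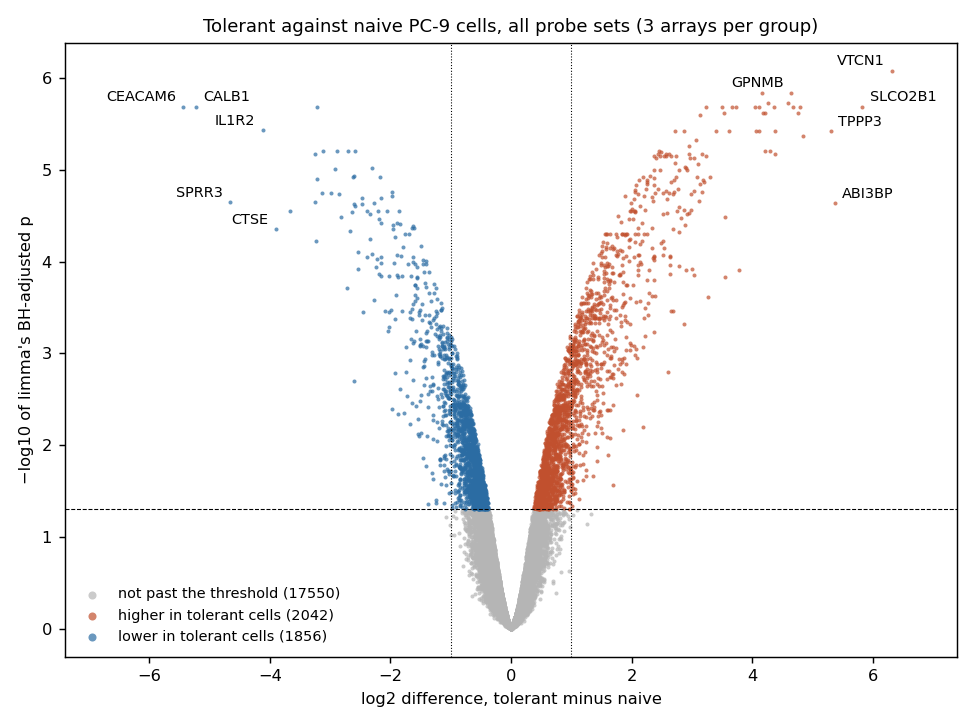
Each point is 1 of 21448 probe sets, with the log2 difference (tolerant minus naive, 3 arrays per group) on the horizontal axis and −log10 of limma's adjusted p on the vertical axis; the dashed line marks an adjusted p of 0.05 and the dotted lines a 2-fold difference. The 2042 higher and 1856 lower probe sets are coloured, and the right side reaches further, up to 6.31 for VTCN1 against −5.44 for CEACAM6.

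The other large rises were those of the microtubule-binding gene TPPP3 (5.30), the oestrogen sulfotransferase SULT1E1 (4.84), the contractile protein gene CNN1 (4.78), the small heat shock protein gene CRYAB (4.75), the endoplasmic reticulum autophagy receptor RETREG1 (4.67), GPNMB (4.64), the doublecortin-like kinase DCLK2 (4.60), the receptor gene GLP2R (4.38) and the pregnancy-specific glycoprotein gene PSG5 (4.38), all as log2 differences with an SE of 0.12 to 0.21. TPPP3, SULT1E1 and CRYAB had a naive mean among the lowest 25% of all probe sets, under 4.73, where a log2 difference can understate the change. PSG5 belongs to a family of near-identical genes, so its value is uncertain. The other large falls were those of the cornified envelope genes SPRR3 (−4.66) and SPRR1A (−3.66), the decoy receptor IL1R2 (−4.12), the protease CTSE (−3.90), the chromatin protein gene HMGA2 (−3.25), CAPN8 (−3.24), the ERK phosphatase DUSP6 (−3.23), the adenosine receptor ADORA2B (−3.22), FAM83A (−3.21) and KRT6C (−3.12), with an SE of 0.11 to 0.28. SPRR3 and CAPN8 had a tolerant mean in that range. Keratin 6 genes are also near-identical copies, so the value of KRT6C is uncertain in the same way.

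Of 20 measured genes in the list of MAPK output, known targets of the cascade downstream of EGFR, 14 were lower and 1 was higher (14 and 1 adjusted over the list alone), with a median log2 difference of −1.24. For the MAPK output list camera gave an adjusted p = 5.48e-08, and adjusted p = 0.122 with an estimated correlation. DUSP6 went from 9.26 ± 0.49 to 6.03 ± 0.17, the transcription factor gene EGR1 from 9.98 ± 0.30 to 7.16 ± 0.23 (−2.82 ± 0.18 SE) and ETV4 from 10.23 ± 0.26 to 8.14 ± 0.37 (−2.09 ± 0.21 SE). IER3 was the member that rose, by 0.45 ± 0.11 SE, a call that ended without any 1 of the 6 arrays (adjusted p from 0.0521 to 0.0916). Among 15 immediate early genes, which also answer to handling, 6 were lower and 1 was higher (7 and 1 adjusted over the list alone, median −0.17). For the immediate early list camera gave an adjusted p = 0.0268, and adjusted p = 0.207 with an estimated correlation. IER2 fell by 1.13 and IER5 by 1.04 on the log2 scale, beside EGR1, and ATF3 rose by 2.64. This list's call ended without naive array 1 (adjusted p = 0.0521), tolerant array 1 (0.056) or tolerant array 3 (0.0639), and with probe sets dimmer than the median left out (0.0767).

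EGFR itself was 13.36 ± 0.12 in naive and 12.79 ± 0.14 in tolerant cells (−0.57 ± 0.13 SE, adjusted p = 0.019), lower in all 3 tolerant arrays than in any naive one. The call ended without naive array 3 (adjusted p = 0.0768), tolerant array 1 (0.061) or tolerant array 2 (0.0719). Neither ERBB3 (0.19 ± 0.12 SE, adjusted p = 0.33) nor MET (0.22 ± 0.12 SE, adjusted p = 0.27) passed the test. AXL, a receptor often studied in EGFR inhibitor tolerance, fell by 0.44 on the log2 scale (SE 0.12), and IGF1R rose by 0.53 (SE 0.13). The AXL call ended without any 1 of the 6 arrays (adjusted p from 0.0626 to 0.127) and with arrays centred on the reference genes (0.112). Without 1 array its log2 difference ran from −0.398 to −0.488. The IGF1R call ended without naive array 3 (0.0902), tolerant array 1 (0.0607) or tolerant array 3 (0.0627). The 14 measured ERBB receptors and ligands had 1 higher and 5 lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.443), with HBEGF at −1.14 and EPGN at −1.06, both EGFR ligands. Of 30 other receptor tyrosine kinases and their ligands, 4 were higher and 3 lower, the same when adjusted over the list alone (camera adjusted p = 0.437): GAS6, the AXL ligand, rose by 2.04 and ROR1 fell by 1.43.

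**Figure D2:**
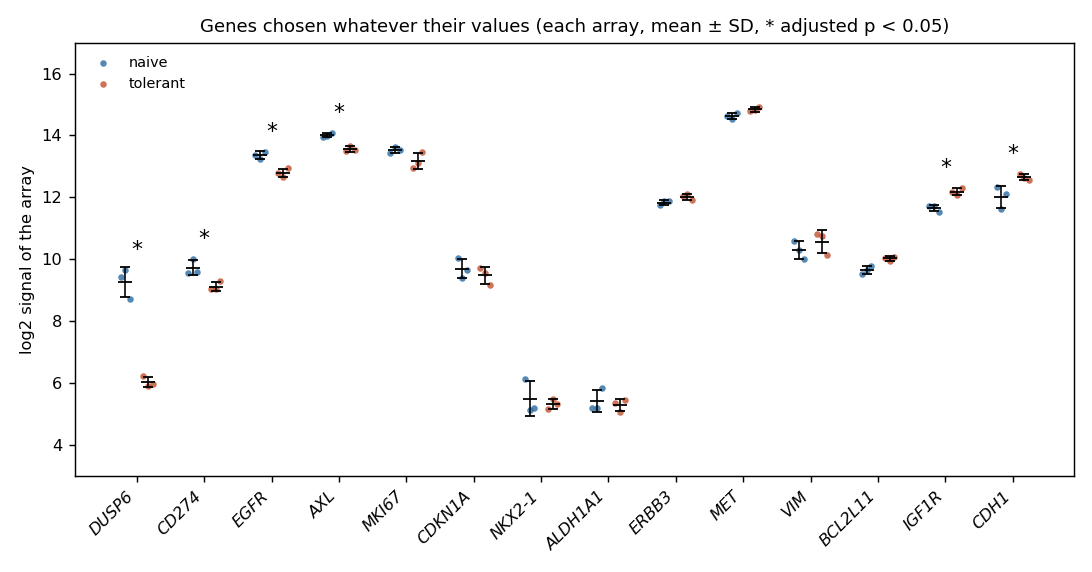
Log2 array signal of the genes named whatever their values, with each array as a point, naive in blue and tolerant in red, and mean ± SD over 3 arrays as bars; stars mark an adjusted p under 0.05. DUSP6 shows the widest gap (9.26 against 6.03), while MKI67 (13.53 and 13.18) and MET (14.63 and 14.85) lie close together.

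Many cell cycle genes fell, by small amounts. Of 36 mitosis genes, 23 were lower and 0 higher (24 and 0 adjusted over the list alone, median −0.58), led by the kinesin KIF2C (−1.23 ± 0.19 SE), the checkpoint gene MAD2L1 (−1.11 ± 0.18 SE) and CDC20 (−0.93 ± 0.13 SE). For the mitosis list camera gave an adjusted p = 2.22e-10, and adjusted p = 0.122 with an estimated correlation. MKI67, the standard marker of cycling cells, was 13.53 ± 0.09 in naive and 13.18 ± 0.26 in tolerant cells, a difference that did not pass (−0.35 ± 0.15 SE, adjusted p = 0.17), and over the other settings its adjusted p ran from 0.0449 to 0.41. DNA replication genes gave 25 lower and 0 higher of 38 (31 and 0 adjusted over the list alone, median −0.60), with ORC1 at −1.52 ± 0.16 SE, CDT1 at −1.30 ± 0.30 SE and GINS2 at −1.06 ± 0.15 SE. For the DNA replication list camera gave an adjusted p = 6.15e-10, and adjusted p = 0.163 with an estimated correlation. The CDT1 call ended without naive array 1 (adjusted p = 0.0592), naive array 2 (0.0523) or tolerant array 1 (0.0547). Replication-dependent histone genes gave 20 lower and 0 higher of 35 (30 and 0 adjusted over the list alone, median −0.64), among them H2BC14 (−1.51), H2BC10 (−1.30) and H4C4 (10.88 to 9.88); these genes are close copies, so single members are uncertain. For the histone list camera gave an adjusted p = 1.04e-09, and adjusted p = 0.245 with an estimated correlation.

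Some genes that hold cells out of cycle rose. Of 20 CDK inhibitor and quiescence genes, 9 were higher and 1 was lower (9 and 2 adjusted over the list alone, median 0.22). For the CDK inhibitor and quiescence list camera gave an adjusted p = 0.00153, and adjusted p = 0.124 with an estimated correlation. CDKN2B, which encodes the CDK4 and CDK6 inhibitor p15, rose from 7.45 ± 0.28 to 10.04 ± 0.15 (2.59 ± 0.17 SE), TXNIP by 1.85 ± 0.15 SE and CCNG2 by 1.78 ± 0.12 SE. The lower member was RBL1 (−0.53), which encodes the pocket protein p107, a call that ended without any 1 array other than tolerant array 3 (adjusted p from 0.0512 to 0.146), with reference-gene centring (0.106) and with array background as a covariate (0.0631). CDKN1A, which encodes p21, did not pass (−0.22 ± 0.20 SE, adjusted p = 0.53), and among 20 p53 target genes 3 were higher and 4 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.958), with TP53INP1 at 1.84 and AEN at −1.18. The 17 measured BCL2 family genes and inhibitors of apoptosis gave 3 higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.208). The pro-apoptotic gene BMF rose by 1.21 and the caspase-8 inhibitor CFLAR by 0.67, while BCL2L11, which encodes BIM, was at 0.37 ± 0.12 SE (adjusted p = 0.074), and over the other settings its adjusted p ran from 0.0222 to 0.178, under the threshold in 5.

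Many genes of growth-related synthesis were lower. Ribosome biogenesis had 22 of 29 members lower and 0 higher (25 and 0 adjusted over the list alone, median −0.66), among them the nucleolar genes NOP2 (−1.21 ± 0.19 SE), NOP16 (−1.07 ± 0.19 SE) and PES1 (−1.04 ± 0.24 SE). The PES1 call ended without any 1 of 3 arrays (adjusted p up to 0.0564). For the ribosome biogenesis list camera gave an adjusted p = 1.04e-09, and adjusted p = 0.128 with an estimated correlation. Of 25 genes of serine, one-carbon and nucleotide synthesis, 11 were lower and 1 was higher (12 and 1 adjusted over the list alone, median −0.31). For the serine, one-carbon and nucleotide list camera gave an adjusted p = 0.000994, and adjusted p = 0.1995 with an estimated correlation. IMPDH2 and IMPDH1, which catalyse the committed step of guanine nucleotide synthesis, fell by 1.12 and 0.97, DHODH of pyrimidine synthesis fell by 1.01, and asparagine synthetase (ASNS) rose by 1.63. Tricarboxylic acid cycle genes gave 7 lower and 1 higher of 19 (9 and 1 adjusted over the list alone, median −0.29), with ACO1, the cytosolic aconitase, at −1.36 ± 0.13 SE, pyruvate carboxylase (PC) at −1.12 ± 0.25 SE, IDH3A at −0.75 ± 0.12 SE and IDH2 at 1.05 ± 0.19 SE. The PC call ended without any 1 of 3 arrays (adjusted p from 0.0558 to 0.0582). For the tricarboxylic acid cycle list camera gave an adjusted p = 0.00823, and adjusted p = 0.265 with an estimated correlation. Fatty acid synthesis and storage genes gave 6 lower and 0 higher of 22 (9 and 3 adjusted over the list alone, median −0.28): the elongase ELOVL6 fell by 1.81, fatty acid synthase (FASN) fell by 1.41 and the lipid droplet protein PLIN2 fell by 0.88. For the fatty acid synthesis list camera gave an adjusted p = 0.0136, and adjusted p = 0.241 with an estimated correlation. This list's call ended without tolerant array 3 (adjusted p = 0.0639) and with probe sets dimmer than the median left out (0.0606), and without naive array 1 that of FASN was 0.0515. Of 27 ribosomal protein genes 1 was lower, RPLP1 (−0.44), and 0 higher (0 and 0 adjusted over the list alone, median −0.15). For the ribosomal protein list camera gave an adjusted p = 0.046, and adjusted p = 0.771 with an estimated correlation. The list's call ended without naive array 1 (0.368) or tolerant array 3 (0.264) and by fry (0.17). It also ended with array weights (0.136), reference-gene centring (0.132) and either filter on dim probe sets (0.0567 and 0.0754). The RPLP1 call ended without any 1 array (0.0624 to 0.0818) and with reference-gene centring (0.0929).

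Many antigen presentation genes rose. MHC class II genes, which normally present peptides on professional immune cells, gave 10 higher and 0 lower of 13, the same when adjusted over the list alone (median 0.86). For the class II list camera gave an adjusted p = 1.65e-07, and adjusted p = 0.122 with an estimated correlation. HLA-DRA went from 7.86 ± 0.40 to 10.74 ± 0.07 (2.89 ± 0.19 SE), HLA-DRB5 rose by 2.75 ± 0.17 SE and HLA-DQB1 by 2.27 ± 0.23 SE; the HLA-DRB and HLA-DQ genes share sequence with their paralogs, so single members are uncertain. Leukocyte markers did not move with them: of 18, 2 were higher and 1 lower (2 and 2 adjusted over the list alone; median −0.05; camera adjusted p = 0.666), with LAPTM5 at −2.89 ± 0.13 SE and ITGAM at 0.76 ± 0.17 SE. The ITGAM call ended without any 1 of 4 arrays (adjusted p from 0.0554 to 0.0696). MHC class I genes gave 9 higher and 1 lower of 17 (10 and 1 adjusted over the list alone, median 0.56), with HLA-E at 1.12, HLA-F at 1.10 and TAPBPL, a peptide editor, at 1.06. For the class I list camera gave an adjusted p = 1.45e-05, and adjusted p = 0.207 with an estimated correlation. The peptide transporter gene TAP2 fell by 0.47, a call that ended without any 1 array other than naive array 2 (adjusted p from 0.0673 to 0.108) and with reference-gene centring (0.0831). Immune checkpoint and natural killer ligands gave 7 higher and 3 lower of 23 (8 and 3 adjusted over the list alone, median 0.14). For the checkpoint ligand list camera gave an adjusted p = 0.0155, and adjusted p = 0.207 with an estimated correlation. Beside VTCN1, LGALS9 rose by 2.06 and CD47, which restrains phagocytosis, by 1.77, while NT5E, which encodes the ectonucleotidase CD73, fell from 15.11 ± 0.07 to 12.95 ± 0.32. CD274, which encodes PD-L1, fell by 0.61 (SE 0.16, adjusted p = 0.031), a call that ended without naive array 2 (0.0814), naive array 3 (0.0592), tolerant array 1 (0.0974) or tolerant array 2 (0.0965), and with arrays centred on the reference genes (0.0628).

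Many inflammatory genes rose. Of 23 NF-kB and cytokine genes, 12 were higher and 2 lower (15 and 3 adjusted over the list alone, median 0.64). For the NF-kB list camera gave an adjusted p = 1.07e-05, and adjusted p = 0.122 with an estimated correlation. The prostaglandin synthase gene PTGS2 rose from 8.28 ± 0.38 to 12.50 ± 0.09 (4.22 ± 0.19 SE), the chemokine gene CCL2 by 4.06 ± 0.16 SE from a naive mean of 3.91, in the lowest 25%, and CXCL1 by 2.37 ± 0.21 SE, whereas IL1B fell by 1.87. Complement and coagulation genes gave 8 higher and 0 lower of 24 (9 and 1 adjusted over the list alone, median 0.27), with the complement protease C1S at 3.54 ± 0.13 SE, factor B (CFB) at 2.91 ± 0.15 SE and protein S (PROS1) at 2.51 ± 0.18 SE. For the complement list camera gave an adjusted p = 0.000721, and adjusted p = 0.122 with an estimated correlation. Type I interferon response genes gave 5 higher and 1 lower of 32, the same when adjusted over the list alone, with no camera call (adjusted p = 0.125), SAMD9L at 1.21 and IFI6 at 1.16.

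Lineage markers changed unevenly. Of 16 squamous and basal markers, 7 were lower and 3 higher (8 and 3 adjusted over the list alone, median −0.45), with the basal keratin gene KRT5 at −2.99 ± 0.17 SE beside SPRR3 and SPRR1A. For the squamous list camera gave an adjusted p = 0.00309, and adjusted p = 0.128 with an estimated correlation. Among the 3 that rose was KRT14 (0.73), from a naive mean of 3.58 in the lowest 25%, a call that ended without any 1 array other than tolerant array 2 (adjusted p from 0.0784 to 0.113). Epithelial identity genes gave 9 higher and 1 lower of 23 (10 and 3 adjusted over the list alone, median 0.27). For the epithelial list camera gave an adjusted p = 0.0268, and adjusted p = 0.265 with an estimated correlation. This call ended without tolerant array 1 (0.0626) and with either filter on dim probe sets (0.0577 and 0.0754). The epithelial transcription factor gene ELF3 had the largest rise, 1.70 ± 0.43 SE (adjusted p = 0.027), a call that ended without any 1 of 4 arrays (0.0797 to 0.0974). The tight junction genes CLDN1 and OCLN rose by 1.52 ± 0.11 SE and 1.15 ± 0.15 SE. The keratin gene KRT18 fell, from 15.58 to 15.04 (−0.54 ± 0.13 SE, adjusted p = 0.022), a call that ended without any 1 of 4 arrays (0.0583 to 0.0704) and with reference-gene centring (0.052). CDH1, which encodes E-cadherin, was 0.63 higher (adjusted p = 0.049), a call that ended without any 1 array other than naive array 1 (0.0855 to 0.143) and with array background as a covariate (0.0709). Mesenchymal genes gave 8 higher and 4 lower of 27 (9 and 4 adjusted over the list alone), with a median of 0.02 and a mean of 0.49. For the mesenchymal list camera gave an adjusted p = 0.0481, and adjusted p = 0.265 with an estimated correlation. TAGLN, an actin-binding protein, rose by 4.36 ± 0.14 SE, fibronectin (FN1) by 2.96 ± 0.14 SE and COL5A1 by 2.41 ± 0.12 SE, SERPINE2 fell by 0.95, and VIM did not pass (0.27 ± 0.22 SE, adjusted p = 0.47). The mesenchymal call ended without naive array 1 (0.0545), naive array 2 (0.0516), tolerant array 1 (0.0878) or tolerant array 2 (0.0858). It also ended with reference-gene centring (0.0979), quantile normalization (0.0513), array background as a covariate (0.13) and the milder filter on dim probe sets (0.0862). No camera call was made for 26 alveolar and club cell genes (2 higher, 2 lower, the same when adjusted over the list alone; camera adjusted p = 0.742), with CLIC5 at 1.45 and MUC1 at 0.98, and the lung lineage factor NKX2-1 had a signal of 5.49 in naive and 5.31 in tolerant cells (adjusted p = 0.72). Of 16 neuroendocrine markers, 1 was higher, SYT1 (0.64), and 0 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.699). The SYT1 call ended without any 1 array other than naive array 2 (adjusted p from 0.0627 to 0.0881).

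YAP and TEAD target genes gave 11 higher and 2 lower of 21 (12 and 2 adjusted over the list alone, median 0.42). For the YAP and TEAD list camera gave an adjusted p = 1.77e-05, and adjusted p = 0.122 with an estimated correlation. ANKRD1, a well-known YAP target, rose from 10.16 ± 0.27 to 13.19 ± 0.21 (3.03 ± 0.17 SE), RBMS3 by 2.68 ± 0.18 SE and GADD45A by 1.62 ± 0.13 SE. The 2 lower members were NT5E and AXL, whose falls are given above, and the AXL call ended without any 1 of the 6 arrays. TGF-beta and BMP response genes gave 8 higher and 3 lower of 20, the same when adjusted over the list alone (median 0.26): SMAD6, an inhibitor of BMP signalling, rose by 2.61, ID3 by 2.47 and the receptor TGFBR1 by 2.26, while PMEPA1 fell by 0.80. For the TGF-beta and BMP list camera gave an adjusted p = 0.00823, and adjusted p = 0.147 with an estimated correlation. WNT and NOTCH target genes had no camera call (2 higher and 3 lower of 22; 3 and 4 adjusted over the list alone; adjusted p = 0.742), although LGR5 rose by 4.21 from a naive mean of 3.71, in the lowest 25%, and the NOTCH target HES1 fell by 1.90.

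Lysosome and autophagy genes gave 12 higher and 1 lower of 27 (15 and 1 adjusted over the list alone, median 0.37). For the lysosome and autophagy list camera gave an adjusted p = 3.7e-05, and adjusted p = 0.207 with an estimated correlation. GABARAPL1, an autophagosome protein of the ATG8 family, rose from 12.49 ± 0.37 to 15.44 ± 0.12 (2.96 ± 0.19 SE), WIPI1 by 1.86 ± 0.17 SE and the proton pump subunit ATP6V1A by 1.34 ± 0.12 SE, while ATG7 fell by 1.13. Unfolded protein and ATF4 response genes gave 10 higher and 2 lower of 23 (11 and 2 adjusted over the list alone, median 0.23), with VLDLR at 3.08 ± 0.16 SE, ATF3 at 2.64 ± 0.22 SE and ASNS at 1.63 ± 0.16 SE. EDEM1 of protein degradation fell by 0.65, a call that ended without any 1 of the 6 arrays (adjusted p from 0.0587 to 0.127), with array weights (0.0752) and with reference-gene centring (0.0965). For the unfolded protein and ATF4 list camera gave an adjusted p = 0.000159, and adjusted p = 0.207 with an estimated correlation. Heat shock genes had no call (1 higher and 1 lower of 13, the same when adjusted over the list alone; camera adjusted p = 0.742), with CRYAB at 4.75 and BAG3 at −0.69; their median of −0.15 and mean of 0.23 differ in sign.

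**Figure D3:**
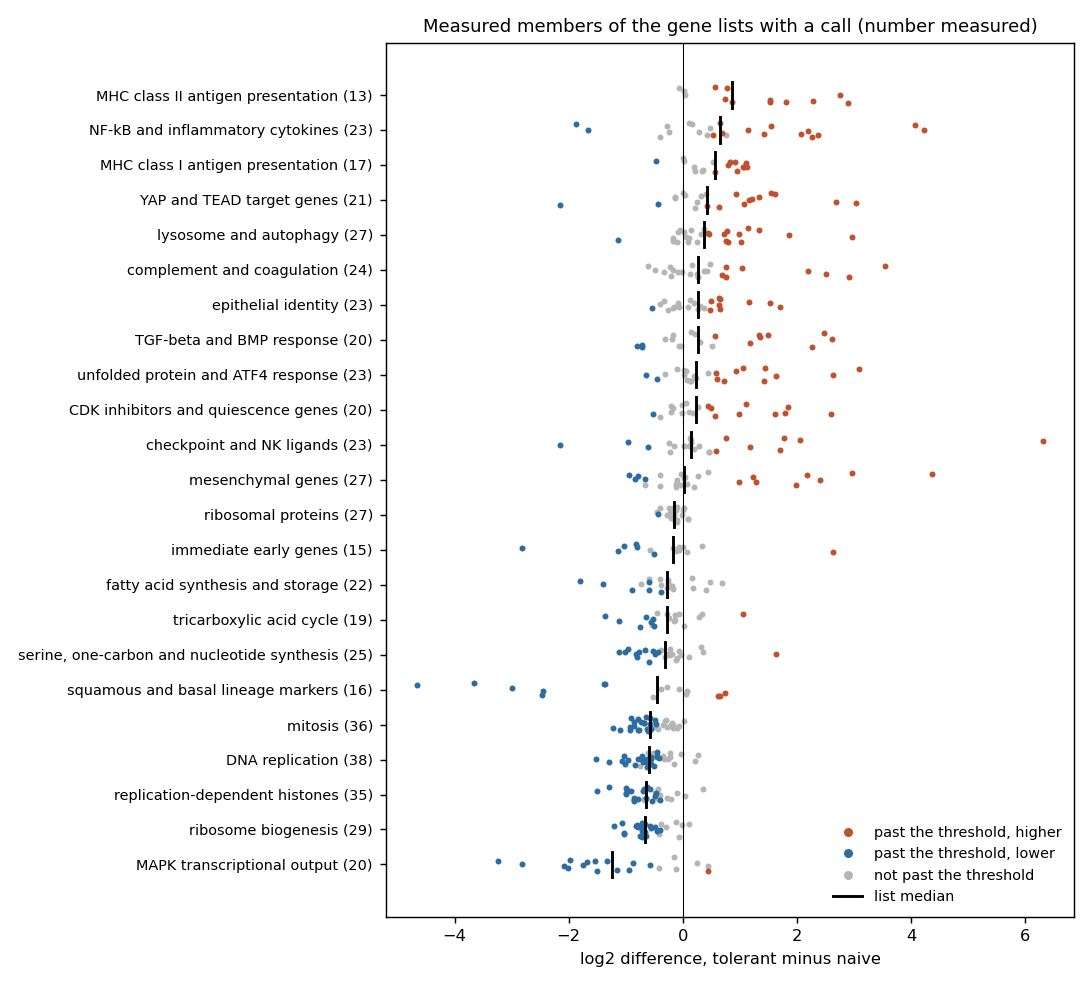
Log2 difference (tolerant minus naive) of each measured member of the 23 gene lists with a camera call, with the number measured in brackets; red and blue points passed the test for single genes, grey points did not, and black bars are list medians. Medians run from −1.24 for the MAPK output genes to 0.86 for MHC class II, and the mitosis and replication members lie close together while the squamous markers spread down to −4.66.

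Other lists drew no camera call. Of 20 aldehyde dehydrogenase and stem cell genes, 3 were higher and 4 lower (3 and 5 adjusted over the list alone; adjusted p = 0.723): beside LGR5, the integrin gene ITGA6 fell by 2.30, and ALDH1A1 did not pass (−0.13 ± 0.20 SE, adjusted p = 0.72). Drug efflux and metabolism genes gave 2 higher and 1 lower of 13, the same when adjusted over the list alone (adjusted p = 0.684), with the efflux pump gene ABCC2 at −2.60 and CYP1B1 at 2.45. NRF2 and glutathione genes gave 3 higher and 4 lower of 27 (3 and 5 adjusted over the list alone; adjusted p = 0.723), with ABCC2 in this list too and TALDO1 at 0.70. The TALDO1 call ended without any 1 of 4 arrays (adjusted p from 0.0597 to 0.0673). Chromatin regulators linked to drug tolerance gave 3 higher and 1 lower of 27, the same when adjusted over the list alone (adjusted p = 0.437), with the deacetylase HDAC5 at 1.64 and the demethylase KDM5B at 0.95. Glycolysis and glucose uptake genes gave 3 higher and 4 lower of 23 (3 and 6 adjusted over the list alone; adjusted p = 0.143), with the glucose transporter SLC2A3 at 3.30 and VEGFA at −0.97. Nuclear genes of the respiratory chain gave 1 higher and 3 lower of 35 (0 and 2 adjusted over the list alone; adjusted p = 0.437), with NDUFC1 at −0.91 and CYC1 at −0.74, and 22 fatty acid oxidation genes gave 0 in either direction by both adjustments, with 4 higher and 4 lower at limma's unadjusted p under 0.05 (camera adjusted p = 0.958).

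Cholesterol synthesis genes gave 5 higher and 0 lower of 19 (5 and 1 adjusted over the list alone; adjusted p = 0.751), with TM7SF2 at 1.58 and SC5D at 0.74. Of 9 LXR target genes 1 was higher, APOE (1.24), and 1 lower, LPCAT3 (−0.57), with 1 and 2 adjusted over the list alone (adjusted p = 0.751). The calls of SC5D (adjusted p from 0.0588 to 0.0739) and LPCAT3 (0.0503 to 0.0754) each ended without any 1 of 4 arrays. Of 15 reference genes 1 was higher, B2M (0.79), which is also a class I gene, and 0 lower, the same when adjusted over the list alone (median −0.07; adjusted p = 0.723). Markers of cells that should be absent gave no camera call. Fibroblast markers had 2 higher, MFAP5 (0.62) and FBLN1 (0.61), and 0 lower of 12, the same when adjusted over the list alone (adjusted p = 0.435). The FBLN1 call ended without any 1 array other than tolerant array 3 (adjusted p from 0.0613 to 0.109) and with array background as a covariate (0.0594). Endothelial markers had 1 higher and 1 lower of 12, the same when adjusted over the list alone (adjusted p = 0.971), with CDH5 at 1.97 and ESAM at −0.88, and erythroid markers had 0 higher and 1 lower of 7 (0 and 3 adjusted over the list alone; adjusted p = 0.166), a list that fry called lower (adjusted p = 0.0477). The lower erythroid marker was ALAS2 (−0.57), a call that ended without any 1 of 4 arrays (adjusted p from 0.0601 to 0.113), with reference-gene centring (0.0541) and with array background as a covariate (0.054). The test's direction was up where the median was below 0 for the neuroendocrine, alveolar, cholesterol synthesis, p53, fatty acid oxidation and endothelial lists. Of the mitochondrially encoded transcripts 0 of 13 had a named probe set, so that list was not analysed here.

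Camera with the preset correlation of 0.01 called 12 lists higher and 11 lower of 46. With an estimated correlation it called 0, with a lowest adjusted p of 0.122 and 11 lists at an unadjusted p under 0.05, while fry called 16 higher and 11 lower, 22 of the 23 camera lists among them in the same direction. The run with an estimated correlation rests on 4 residual degrees of freedom, so its loss of calls does not measure correlation alone. Where a list had 0 calls in a direction, limma's unadjusted p was under 0.05 for 3 higher fatty acid synthesis genes, 1 lower complement gene, 1 higher erythroid marker, 2 lower reference genes and 3 lower cholesterol synthesis genes. In the mitosis, replication, ribosome biogenesis, histone, class II, ribosomal protein, fibroblast and neuroendocrine lists that count was 0 as well. Centring the arrays on the reference genes moved the median difference of all probe sets from −0.04 to 0.06 and the share of calls that were higher from 52.4% to 68.3% (2623 higher, 1218 lower), a shift of 0.103 that applies to every difference given here; no called list or called named gene changed direction under it.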

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

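The covariate for array background and the filter on the higher group mean were chosen after the data had been seen. Under all settings run, no list or named gene with a call turned its direction. At an adjusted p under 0.01, 1163 probe sets were higher and 772 lower; a stricter threshold calls fewer by construction. Centred on the reference genes, 1218 were lower, and the cause is the scaling, which shifted all differences by 0.103. Other settings called more: 2522 higher and 2519 lower with a trended robust prior, 2380 and 2304 with array weights, 2271 and 2189 with the filter on the higher group mean, 2263 and 2190 without probe sets under the 25th percentile. Quantile normalization gave 2053 and 2036. The excess of higher calls turned into one of lower calls without probe sets dimmer than the median (2146 and 2383) and was gone with the covariate (2058 and 2059). With 1 array left out, the count of lower probe sets ran from 1107 to 1474, against 1856 with all arrays, and of higher ones from 1429 to 1707; without naive array 3 it was 1107 lower and without tolerant array 2 it was 1203, both fits having fewer samples. The 2-fold counts then ran from 745 to 805 higher and from 321 to 375 lower. Camera called 0 lists higher and 0 lower with an estimated correlation, against 12 and 11. A stronger correlation between genes is not the cause for every list. The estimate was under the preset 0.01 for class II (−0.065) and complement (−0.0294). Their unadjusted camera p still rose, from 2.16e-08 to 0.0041 and from 0.000188 to 0.014. Other called lists had estimates above the preset, up to 0.488 for ribosomal proteins. With an estimated correlation camera also takes its p from the 4 residual degrees of freedom, not from the number of genes. That raises p even without a stronger correlation. Fry alone called the interferon, BCL2 family, drug efflux, erythroid and WNT and NOTCH lists.

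The replicate numbers did not pair the arrays: deviations from the group means of same-numbered arrays correlated at 0.104, −0.203 and 0.135, and not every array correlated best with its own number. The fit with a replicate block called 1729 probe sets higher and 1484 lower, 756 and 348 at 2-fold or more, and 11 lists higher and 10 lower. It made no call for the mesenchymal and ribosomal protein lists (adjusted p = 0.0656 and 0.0561) and for 8 named genes called without it: ALAS2, AXL, CD274, IER3, IGF1R, RBL1, RPLP1 and TAP2 (0.0513 to 0.0842).

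Leaving aside the estimated correlation, 18 of the 23 list calls held in all settings, with adjusted p up to 0.0493, and 5 were lost in at least 1. These 5 had adjusted p from 0.000645 to 0.13 (mesenchymal, lost in 9), 0.0027 to 0.368 (ribosomal proteins, 8), 0.00169 to 0.0767 (immediate early, 4), 0.00598 to 0.0754 (epithelial, 3) and 0.00589 to 0.0639 (fatty acid synthesis, 2). Of the 141 named genes past the threshold, 117 held in all settings that tested them and 24 lost the call in at least 1. Dim probe sets limit the small differences: without detection values, signal over background was not measured.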

Other observations

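The gene families in the next paragraph, the tests of leukocytes, CIITA and fibroblasts, and the covariate and filter named above were chosen after the results had been seen. The other tests on the contractile and cell cycle genes were not among the planned ones either and address patterns seen in the results. The leukocyte and fibroblast tests were first run on the full marker lists and then restricted to markers dim in naive cells; both versions are given. The condition on the brightness of CIITA was added after its value had been seen.

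Grouping genes by the root of their symbol gave 613 families with 5 or more measured members, of which camera at the preset correlation called 13 higher and 16 lower, and 0 with an estimated correlation. Pregnancy-specific glycoprotein genes led: 9 of 10 PSG genes were higher (median 1.59; camera adjusted p = 1.49e-08; adjusted p = 0.907 with an estimated correlation), with PSG1 going from 5.15 to 8.39 and PSG8 from 4.91 to 7.94. These genes are near-identical copies, so the number of distinct genes that rose is uncertain. Their estimated correlation was −0.032, under the preset, so correlation does not explain their adjusted p of 0.907. Camera with an estimated correlation had 4 residual degrees of freedom and adjusted over 613 families. It could therefore hardly call any family, these and those below included. Part of the mitochondrial ribosomal protein genes fell. Of 47 MRPL genes, 23 were lower (median −0.457, camera adjusted p = 0.909 with an estimated correlation). Of 27 MRPS genes, 8 were lower (median −0.307, camera adjusted p = 0.907 with an estimated correlation). Genes with the symbol root RPL had 0 higher and 1 lower of 34 (median −0.148), and those with RPS 3 higher and 2 lower of 34 (median −0.105). A shared root can take in genes that do not encode ribosomal proteins. The fixed list of 27 ribosomal protein genes had 0 higher and 1 lower (median −0.15). The difference between the mitochondrial families and these was not tested. Butyrophilin genes (5 of 7 higher, median 0.937), guanylate-binding protein genes (4 of 7, median 0.943), mu-class glutathione transferase genes (4 of 5, median 0.737), YPEL genes (4 of 5, median 1.12) and intraflagellar transport genes of cilia (9 of 18, median 0.36) were called higher, each with adjusted p = 0.907 with an estimated correlation. Named among them after their values were seen, BTN3A2 went from 12.06 to 13.08, GBP1 from 9.69 to 11.26 and YPEL5 from 11.67 to 13.34. Cornified envelope genes of the SPRR family fell (6 of 10, median −1.18), and so did 4 of 9 SSX genes (median −0.63), a cancer-testis family of close copies (both adjusted p = 0.907 with an estimated correlation).

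The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For each of 3 counts, 1 of the 10 splits, the real one, gave as many: 3898 probe sets past the threshold (highest other split 0), 1108 at 2-fold or more (highest other split 0) and 23 lists (highest other split 13). Other splits had up to 1647 probe sets at limma's unadjusted p under 0.05. Every other split sets 2 arrays of 1 group and 1 of the other against the rest. Part of the real difference stays in such a contrast, and the remainder adds to the spread within its sides. The counts in these splits, the 13 camera lists included, therefore do not measure false calls.

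Of 13 MHC class II genes 10 were higher and 0 lower, with a median of 0.857 (camera adjusted p = 1.65e-07; adjusted p = 0.122 with an estimated correlation). Leukocytes in the tolerant cultures would bring their own abundant transcripts, and the 6 of these that are dim in naive cells had a median of −0.175 (95% bootstrap interval −0.427 to 0.118; −0.26 for all 11, −0.437 to 0.0767), which argues against them. CIITA, the class II transactivator, went from 6.42 to 6.45 (log2 difference 0.0267, 95% limma interval −0.4 to 0.454). A rise of its RNA remains open, since signal over background was not measured and its probe set is dimmer than the median of 7.19. Osimertinib treatment itself, the difference the design names, was not tested apart from the culture time it came with.

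The contractile genes CNN1, TAGLN and MYL9 rose strongly. MYL9, TPM1, CALD1, ACTA2, ACTB, SRF, FHL2, CCN1 and CCN2 are named after their values were seen. Smooth muscle cells would raise their markers together, but 13 of these had a median of −0.00667 (−0.183 to 0.17), and 7 fibroblast transcripts dim in naive cells had a median of −0.203 (−0.303 to 0.18; −0.0367 for all 10, −0.253 to 0.313), which argues against either cell type. The other 21 measured targets of SRF and myocardin-related factors, a transcription pathway that senses actin, had 9 higher and 0 lower. Their median was 0.353 (0.18 to 0.733). Camera gave them an unadjusted p = 3.2e-07, and an unadjusted p = 0.0145 with an estimated correlation. With that estimate, 11 of the fixed lists also had an unadjusted p under 0.05, and 0 were called after adjustment. A rise of part of this programme, including TPM1 and CALD1, is therefore a candidate explanation, as a hypothesis found and tested on the same arrays. Most of the 21 did not pass, among them ACTB (0.08), SRF itself (−0.06) and FHL2 (−0.38). CCN1 and CCN2, which rose, are also in the YAP and TEAD list. ACTA2, another target, differed by 0.02.

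Cell cycle genes fell by small amounts: of 74 mitosis and replication genes, 48 were lower and 0 higher, with a median of −0.583. Centring the arrays on the reference genes moves every gene by the same 0.103, and the median was then −0.48. This argues against scaling that the reference genes can show as the cause. A shift that the reference genes share cannot be seen this way. Compressed signal of bright probe sets may shrink the falls and remains open. Brighter members fell less (Spearman's rho across genes 0.455, permutation p = 1e-04, the smallest that 9999 permutations can give), but the SD of differences among all genes as bright as the brighter members was 0.746 times that among genes as bright as the dimmer ones (0.517 against 0.693), between the bounds set for either answer. The permutation treats genes as independent, so its p can be too small where genes vary together. No biological explanation was tested for the size of these falls.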
